A study of Rattus norvegicus with 7 samples.

How the data were processed

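Lung RNA was measured in 7 samples on Affymetrix rat expression arrays, 3 in the HSU group (hypoxia and SU5416) and 4 in the HSU_Sor group (hypoxia, SU5416 and sorafenib). Per the labels' protocols, the pulmonary vessels were perfused with saline, the right lung was frozen, total RNA was extracted with Trizol, and biotin-labelled RNA was hybridised. The authors deposited log2 expression values per probe set, already normalized across arrays. Per the submitters' processing notes, RMA and GCRMA were used. Which of them made these values, and in which version, is not given in the sources used here. The values ran from 0.29 to 16.14, the lower quartile of each array lay between 2.37 and 2.42, and genes not expected in lung lay at a floor (Ins2 at 1.61, Pomc at 2.05) while lung genes were high (Sftpc at 15.47, Scgb1a1 at 15.89). Each array's median lay between 3.59 and 3.68 on the log2 scale. Differences of dim probe sets are compressed at this floor.

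The 57 control probe sets were left out. Their names did not go with their values: the control named for the 3' end of beta-actin had a mean of 2.72 and that for the 3' end of hexokinase 12.36, while a probe set shared by Actb and its close relatives was at 15.47. RNA integrity could therefore not be read from the 3' and 5' controls. Of the 31042 other probe sets, 20826 had 1 gene symbol in the platform annotation, 436 had several and 9780 had none. Symbols were updated through gene identifiers to the RefSeq gene table of assembly GRCr8, which matched 20758 probe sets and changed 0 symbols. No probe set with several symbols was named, and no coordinates were used.

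The comparison was HSU_Sor minus HSU, fitted with limma (version 3.58.1, lmFit and eBayes, R version 4.3.3) on the deposited log2 values, two-sided, with no covariate. It ran on the 15521 probe sets whose mean over the 7 arrays was above the median of all non-control probe sets (3.64), with Benjamini-Hochberg adjustment and a threshold of 0.05. A second count used an unadjusted p below 0.01 and a fold of at least 1.4. Gene lists were tested with limma camera at a preset inter-gene correlation of 0.01 on 14217 genes with 1 probe set each, the one with the highest mean, and with Benjamini-Hochberg over 32 lists. These comprised sorafenib targets, ERK signalling, immediate early, smooth muscle, extracellular matrix, endothelial, angiogenic, HIF target, proliferation, inflammation, interferon, macrophage, T and NK cell, B and plasma cell, mast cell, neutrophil, cardiac muscle, alveolar type I and type II, airway secretory, ciliated, erythroid, platelet, vasoactive, BMP and TGF-beta, clock, aryl hydrocarbon receptor and NRF2 target, heat shock, adipocyte, mesothelial, skeletal muscle and sex chromosome genes. Each test was repeated with an estimated correlation. List members were also tested in a limma fit over all 31042 non-control probe sets and adjusted over the list alone. SEs are those of the fit on 15521 probe sets wherever the gene was in it.

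The comparison, the lists, the rule for named genes and the alternatives below, unless stated otherwise, were fixed before the data were examined. Named genes were, per direction, the 12 with the largest fold past the adjusted threshold and with groups that did not overlap. As none passed, the places went to the genes with the smallest unadjusted p among those with a fold of at least 1.4 and groups that did not overlap. Each gene was represented by 1 probe set, the one with the highest mean over the 7 arrays. Up to 4 members of each list with the smallest unadjusted p, and any member of the sorafenib target and ERK lists, could be named as well. A further 4 lists (liver, sterol synthesis, LXR target and pericyte genes) were written after the values were seen and were adjusted as a family of their own.

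Alternatives were no filter, a filter at the 75th percentile, quantile normalization, median centring, an intensity trend with robust hyperparameters, array weights, 1 probe set per gene, the mean of probe sets per gene, list members above the median alone, a block on the replicate number, and each array left out in turn. The SAM statistic, with a minimum fold of 1.4 and all 35 splits, was a further alternative, since the series description names SAM. It was written anew for this purpose, and the series description gives no settings beyond the delta and the minimum fold. After the data were seen, fits without HSU 1b and 2b and without HSU_Sor 3 and 4 were added. A larger offset before taking logs, planned for linear values, did not apply. On simulated data with the means and spreads of this comparison on 15521 probe sets and 200 changed probe sets per draw, limma recovered 34.6% of those changed 1.4-fold, 70.4% of those changed 2-fold and 88.8% of those changed 4-fold, with 49 false calls among 694 over 5 draws. In the same kind of simulation on 14217 genes, camera called a smooth muscle list lowered by 0.5 in 20 of 20 draws, and 1 of 620 tests of unchanged lists was called. SAM called 202 probe sets where 200 of 15521 were changed 4-fold and 0 where none was. All these simulations drew each gene independently of the others. In the data the correlation estimated within the smooth muscle list was 0.39. The rate of false calls on the real arrays, of lists above all, can therefore not be read from them. The simulations also took each gene's fitted spread as its true spread, and the number and size of the changes were chosen. The shares recovered therefore do not give the power on the real arrays.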

Results

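The 7 arrays measured total RNA from perfused right lungs of Dahl salt-sensitive rats, an inbred strain that develops hypertension on a high-salt diet. The labels name this strain for all 7 samples, while the treatment protocol refers to samples per strain without naming other strains. All 7 arrays came from rats kept in hypoxia (inspired oxygen about 9.5%) and given SU5416, an inhibitor of VEGF receptors, with lungs taken at 3.5 weeks. Hypoxia with SU5416 is a rat model of pulmonary arterial hypertension. The HSU group (3 arrays) received hypoxia and SU5416, and the HSU_Sor group (4 arrays) received sorafenib as well, an inhibitor of RAF kinases and of receptor tyrosine kinases that include the VEGF and PDGF receptors. The study design also describes arrays of normoxic rats and of rats in hypoxia alone, which were not analysed here. Each array carried 31042 non-control probe sets, with a median log2 expression between 3.59 and 3.68, and correlations between arrays over the 15521 probe sets tested lay between 0.9843 and 0.9916. The small number of arrays limits the precision of every value. The study design counts rats per group, and each array was taken to be from its own rat. Replicate numbers carry the letter b in every HSU title and in no HSU_Sor title, so a batch marked by this letter and the treatment cannot be told apart. HSU 1b and 2b also had signal at probe sets of MHC genes that was at the floor on the other 5 arrays, for RT1-Bb at 12.57 on both against 3.55 to 3.72.

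The comparison asked which lung transcripts differed when sorafenib was added to hypoxia and SU5416. Transcripts of smooth muscle cells and of the extracellular matrix were lower as groups in HSU_Sor lungs with the preset correlation of limma camera. Neither list passed with an estimated correlation (adjusted p = 0.452 for smooth muscle and adjusted p = 0.201 for matrix). Desmin (Des), the muscle intermediate filament, was at 11.53 ± 0.06 (SD, n = 3) on the log2 scale in HSU and at 10.43 ± 0.21 (SD, n = 4) in HSU_Sor, a 2.14-fold lower level. Smooth muscle gamma-actin (Actg2) was 2.73-fold lower, and the prostacyclin synthase Ptgis, which makes a vasodilator, was 2.04-fold lower. The matrix glycoprotein tenascin-C (Tnc) was 3.74-fold lower, and the complement component C1qc, made by macrophages, was 3.20-fold lower. In each of these 5 genes every HSU_Sor array lay below every HSU array. For Des, Actg2 and Ptgis this was a condition of being named, and Tnc and C1qc were named for a small p within their lists. Of all probe sets tested, 5.3% had groups that did not overlap, against 5.7% expected by chance.

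No single probe set passed the adjusted threshold. With limma, 0 of 15521 probe sets had an adjusted p below 0.05, the lowest adjusted p being 0.15. Without HSU replicate 3b, 6 probe sets passed, all lower in HSU_Sor, and each of them with a single gene symbol was of an MHC (RT1) gene. At an unadjusted p below 0.05 there were 931 probe sets, 362 higher and 569 lower in HSU_Sor, where chance alone would give about 776. At a fold of at least 1.4 and an unadjusted p below 0.01 there were 131, of which 36 were higher and 95 lower. The SAM statistic with all 35 splits of the arrays and the same minimum fold called 42 probe sets at an estimated false discovery rate of 4.59%, 1 higher and 41 lower, and 61 at 6.33%. At the delta of 0.639 given in the series description it called 106, of which 9 were higher and 97 lower, at 12.7%. The series description gives 38 genes at a rate of 6.7% for this pair of groups. Groups did not overlap for 816 probe sets, 5.3% of those tested, against 5.7% expected by chance.

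The 12 genes with the smallest unadjusted p among those lower by at least 1.4-fold, with groups that did not overlap, did not pass the adjusted threshold over all probe sets. Each gene stood for its probe set with the highest mean. A dimmer probe set of caldesmon (Cald1), at -0.78 ± 0.09 (SE), had an adjusted p of 0.15 as well. The named genes' adjusted p ranged from 0.15 to 0.416. After Ptgis (log2 difference -1.03 ± 0.10, SE), Des (-1.10 ± 0.12) and Actg2 (-1.45 ± 0.16) came Ankrd1, a muscle ankyrin repeat protein (-1.38 ± 0.16), and Plod2, a lysyl hydroxylase of collagen (-1.21 ± 0.15). The connexin Gjc1 differed by -0.85 ± 0.11 and the high-density lipoprotein receptor Scarb1 by -0.73 ± 0.10. Clec10a, a lectin of macrophages and dendritic cells, differed by -1.45 ± 0.24. The calcium-binding protein Calu differed by -0.55, Dkk3 by -0.79, Olfml2b by -1.14 and Lypd2 by -0.93. With probe sets above the 75th percentile alone, Ptgis, Des, Actg2 and Ankrd1 passed, each with an adjusted p of 0.0441.

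The 12 genes higher in HSU_Sor by the same rule did not pass the adjusted threshold either, with adjusted p from 0.15 to 0.57. Ociad2 was higher by 0.55 ± 0.06 (SE) on the log2 scale, the collagen VI chain Col6a5 by 0.90 ± 0.13 and the cholesterol exporter Abca1 by 0.74 ± 0.12. Ptprr, a phosphatase that acts on ERK kinases, was higher by 0.74 ± 0.13. Chst12, a sulfotransferase of chondroitin, was higher by 0.74, and the proteoglycan osteoglycin (Ogn) by 0.66. Exoc3l2 was higher by 1.38 ± 0.30, 2.61-fold. The remaining genes were Ecm2 (0.65), Ass1 (0.60), Mink1 (0.57), Cyp2s1 (0.54) and the monocarboxylate transporter Slc16a7 (0.52). The other probe sets of the named genes gave no opposite difference at an unadjusted p below 0.05.

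**Figure D1:**
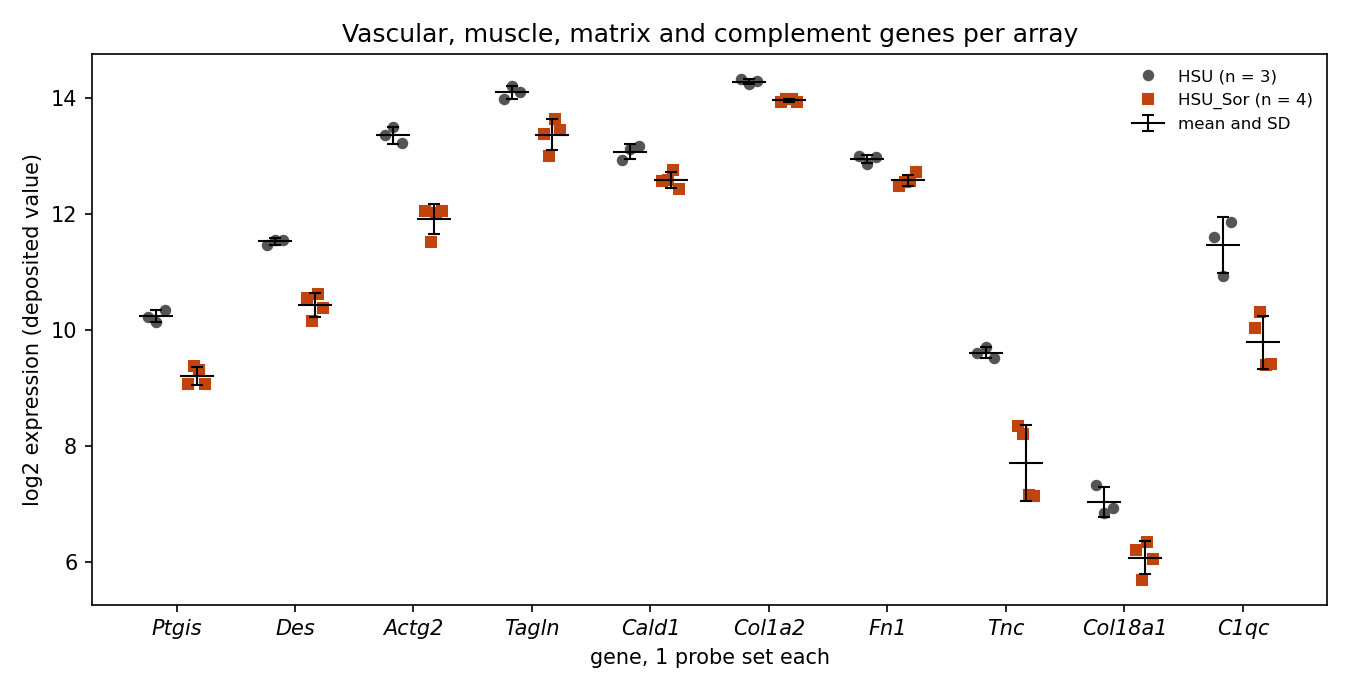
Deposited log2 expression (vertical axis) of 10 genes (horizontal axis), with a circle for each HSU array, a square for each HSU_Sor array, and the mean with its SD in black. For all 10 genes every HSU_Sor array lies below every HSU array, as for Tnc, where HSU has a mean of 9.61 and HSU_Sor of 7.71. The genes were named for this separation or for a small p, so the separation is no test.

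Of the 32 gene lists, 12 passed the threshold of limma camera, 8 lower and 4 higher in HSU_Sor, and 0 passed with an estimated correlation. Without HSU_Sor replicate 2 there were 7, and without HSU replicate 3b there were 8. Smooth muscle contractile genes fell as a list, with a median log2 difference of -0.49 over 15 genes (limma camera, adjusted p = 7.51e-12 with the preset correlation). The adjusted p = 0.452 with an estimated correlation, at an unadjusted p of 0.0283. Of the 15 genes, 8 were lower at an adjusted p below 0.05 adjusted over the list alone, 7 did not pass, and 0 passed over all probe sets. Des and Actg2 had a list-alone adjusted p of 0.000687, the transgelin gene Tagln (-0.72) of 0.0113 and caldesmon (Cald1, -0.49) of 0.00935. Acta2, the alpha-actin of smooth muscle, differed by -0.04 ± 0.14 (SE) and Myh11, its myosin heavy chain, by -0.27 ± 0.18. Acta2 and Myh11 were picked after their values were seen. The sign of Acta2 turned to 0.03 with quantile normalization and to 0.04 at most without an array, and Myh11 was at -0.17 without HSU_Sor replicate 2.

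Extracellular matrix genes fell as a list, with a median of -0.46 over 25 genes (adjusted p = 1.66e-15). The adjusted p = 0.201 with an estimated correlation, at an unadjusted p of 0.00629. Adjusted over the list alone, 15 genes were lower, 0 were higher and 10 did not pass, and 0 passed over all probe sets. The collagen chain Col1a2 differed by -0.32 ± 0.05 (SE) and fibronectin (Fn1) by -0.36 ± 0.07. Tnc differed by -1.90 ± 0.35 and Col18a1, the precursor of endostatin, by -0.96 ± 0.18. Both lists stayed past the threshold without each of the 7 arrays in turn. A list score is the mean log2 deviation of an array from the 7-array mean. It covers only list genes above the filter on mean expression, here 14 smooth muscle and 25 matrix genes. The mean score of each list was below every HSU array in all 4 HSU_Sor arrays. The two-sided exact permutation p was 0.0571, the smallest that 3 against 4 arrays can give. The scores of mast cell, airway secretory, ERK signalling and sex chromosome genes separated the groups as fully, with the same exact p.

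Cardiac muscle genes fell as a list (20 genes, median -0.42, adjusted p = 0.000251, adjusted p = 0.537 with an estimated correlation). Over the 9 genes above the filter, HSU 3b scored -0.57 and the HSU_Sor arrays between -0.79 and -0.15. The list scores of HSU replicates 1b and 2b were 1.38 and 0.99. Myoglobin (Mb) was at 6.88 and 5.59 on those arrays and at 2.57 on HSU 3b, and its log2 difference of -2.38 was -1.45 without HSU replicate 1b and -3.60 without HSU replicate 3b. Ankrd1 was the only gene of the list past its threshold adjusted over the list alone (adjusted p = 0.00265), and 0 passed over all probe sets. It was at 10.63, 10.96 and 10.51 on HSU 1b, 2b and 3b and between 9.01 and 9.55 in HSU_Sor. Ankrd1 thus stayed high on HSU 3b, where the cardiac score was low. The list passed without each array in turn, but without HSU replicate 1b its median was -0.02 (adjusted p = 0.0203), and without the HSU arrays 1b and 2b together its median was 0.01. Smooth muscle scores of the HSU arrays were 0.24, 0.39 and 0.32 and did not follow the cardiac scores. The matrix scores of the same arrays were 0.35, 0.25 and 0.24, in the order of the cardiac scores.

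Mast cell genes fell as a list of 10 (median -0.17, adjusted p = 0.00681, and adjusted p = 0.537 with an estimated correlation). The mast cell protease Mcpt10 was 5.36-fold lower and the only gene of the list to pass adjusted over the list alone (adjusted p = 0.0483). Carboxypeptidase A3 (Cpa3) differed by -0.74. Over the 5 genes above the filter the list score was 1.13 on HSU 2b against 0.15 and 0.26 on the other HSU arrays. Without HSU replicate 2b the median was -0.04 and the call was lost (adjusted p = 0.0652). The mast cell median was -0.29 without HSU replicate 1b and -0.31 without HSU replicate 3b. Macrophage genes fell as a list of 16 (median -0.12, adjusted p = 0.0197, and adjusted p = 0.537 with an estimated correlation), and 1 of them, C1qc, passed adjusted over the list alone (adjusted p = 0.0324). The other chains of the same complement protein, C1qa and C1qb, differed by -1.70 ± 0.43 and -2.69 ± 0.84 (SE). Of the 16 genes, 12 were lower and 4 higher, the latter being Cd68 (0.39), Csf1r (0.17), Cd14 (0.07) and Mrc1 (0.01). These 4 were picked after their values were seen. The macrophage call was lost without HSU replicate 1b (adjusted p = 0.0788), HSU replicate 3b (0.298) or HSU_Sor replicate 3 (0.0634), with medians of -0.04, -0.03 and -0.10, and the median was -0.25 without HSU replicate 2b. For both lists 0 genes passed over all probe sets.

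Interferon-stimulated genes fell as a list of 15 (median -0.51, adjusted p = 0.00681, and adjusted p = 0.537 with an estimated correlation), with 0 genes past the threshold adjusted over the list alone. HSU 3b carried this call, with a score of 1.36 against -0.30 and -0.18 on the other HSU arrays and values between -0.41 and -0.09 in HSU_Sor. Mx2 was at 11.79 on HSU 3b and at 10.32 and 10.48 on HSU 1b and 2b, and differed by -0.26 without HSU replicate 3b. Without HSU replicate 3b the median was -0.01 and the adjusted p 0.373, and without HSU_Sor replicate 4 the adjusted p was 0.0552. Erythroid genes fell as a list of 11 (median -0.07, adjusted p = 0.0197, and adjusted p = 0.537 with an estimated correlation), again with 0 genes past the threshold adjusted over the list alone. Only 3 of the 11 were above the filter, so the medians of this list come mostly from probe sets near the floor. Hemoglobin beta (Hbb) was at 12.11 on HSU_Sor 3 and 11.59 on HSU_Sor 4, and between 14.23 and 14.75 on the other 5 arrays, and differed by -0.70 without HSU_Sor replicate 4. The erythroid call was lost without HSU replicate 1b (adjusted p = 0.0993), HSU replicate 2b (0.0883) or HSU_Sor replicate 3 (0.189), with medians of -0.03, -0.07 and -0.04. Heat shock genes fell as a list of 9 (median -0.26, adjusted p = 0.00989, and adjusted p = 0.537 with an estimated correlation), with 0 genes past the threshold adjusted over the list alone and Hspb1 at -0.31. That call was lost without HSU replicate 1b (0.0677), HSU replicate 3b (0.2), HSU_Sor replicate 1 (0.0955) or HSU_Sor replicate 2 (0.0519), with medians between -0.22 and -0.16.

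Of the lists that rose, transcripts that follow ERK signalling had a median of 0.14 over 13 genes (adjusted p = 0.00657, and adjusted p = 0.491 with an estimated correlation). None of the 13 passed adjusted over the list alone. Phlda1 was at 6.45 ± 1.20 (SD, n = 3) in HSU and 8.49 ± 0.96 (SD, n = 4) in HSU_Sor, and Myc differed by 0.14. The ERK call was lost without HSU_Sor replicate 2 (median 0.08, adjusted p = 0.0784). Proliferation genes rose as a list of 27 (median 0.18, adjusted p = 0.000251, and adjusted p = 0.537 with an estimated correlation), with 0 genes past the threshold adjusted over the list alone. Cdk1, the kinase that drives mitosis, was 2.10-fold higher with overlapping groups (log2 difference 1.07, and 0.59 without HSU replicate 3b), and the list scores were 0.56 and 0.73 on HSU_Sor 1 and 2 and -0.52 and -0.08 on HSU_Sor 3 and 4. The proliferation call was lost without HSU replicate 3b (adjusted p = 0.0728) or HSU_Sor replicate 2 (0.0658), with medians of 0.13 and 0.11, and the median was 0.29 without HSU_Sor replicate 4. Aryl hydrocarbon receptor and NRF2 target genes rose as a list of 11 (median 0.16, adjusted p = 0.0105, and adjusted p = 0.467 with an estimated correlation), with Gclm at 0.24. That call was lost without HSU replicate 2b (0.192) or HSU_Sor replicate 2 (0.0658), with a median of 0.09 in both. The sex chromosome list of 3 genes rose by a median of 0.14 (adjusted p = 0.0356, and adjusted p = 0.467 with an estimated correlation) and passed in 1 of the 7 fits that left out an array, that without HSU_Sor replicate 4, with an adjusted p of up to 0.0994 in the others. For the last 2 lists 0 genes passed adjusted over the list alone.

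**Figure D2:**
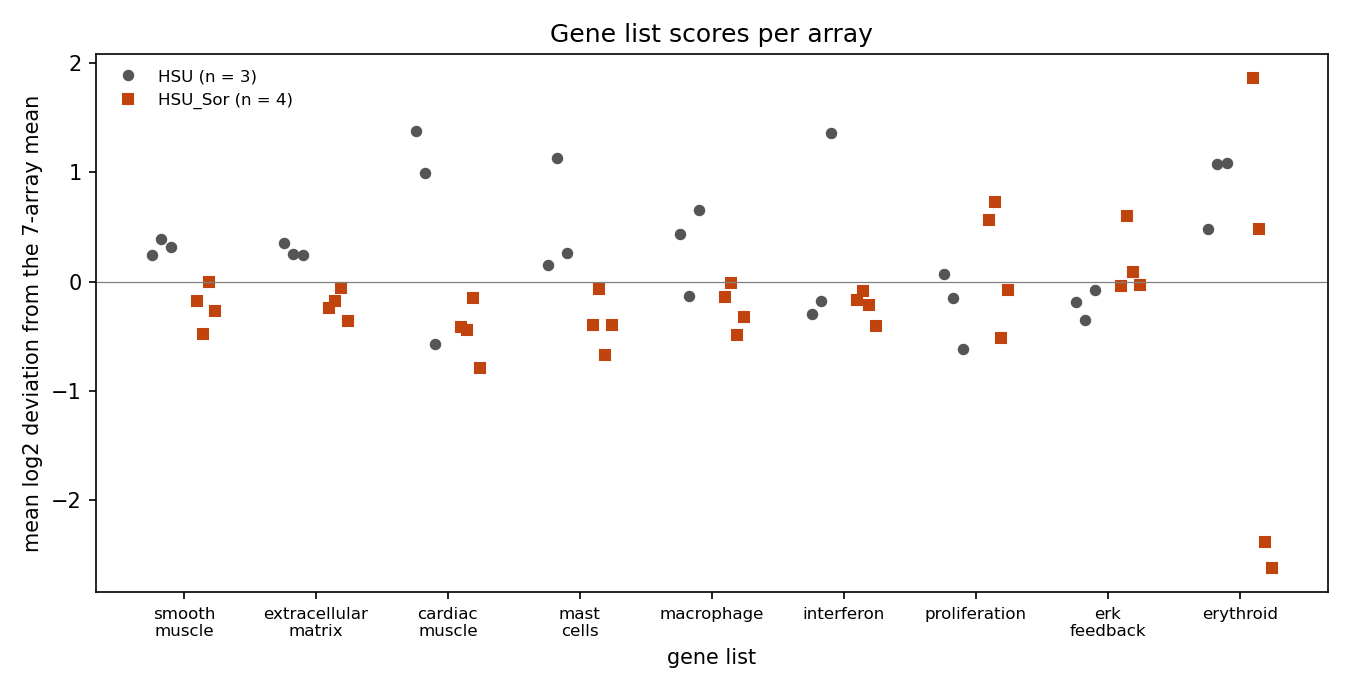
Mean log2 deviation of each array from the 7-array mean (vertical axis) for 9 lists (horizontal axis), with circles for HSU and squares for HSU_Sor arrays. Each score covers only the list genes above the filter on mean expression, 3 for the erythroid and 9 for the cardiac list. The smooth muscle and matrix scores separate the groups, the cardiac list sets HSU 1b (1.38) and 2b (0.99) apart, the interferon list sets HSU 3b (1.36) apart, and the erythroid list sets HSU_Sor 3 (-2.38) and 4 (-2.62) apart.

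The remaining 20 lists did not pass. Kinases that sorafenib inhibits had a median of -0.04 over 14 genes (adjusted p = 0.624). Among them the PDGF receptor Pdgfrb differed by -0.95 ± 0.42 (SE), Kdr by 0.12 ± 0.19, Flt1 by -0.26 ± 0.20 and Csf1r by 0.17 ± 0.12, and 0 passed adjusted over the list alone. Without HSU_Sor replicate 4, Pdgfrb differed by -0.60, Flt1 by -0.09 and Kdr by 0.27. Kdr was at 0.01 without HSU replicate 1b and 0.02 without HSU_Sor replicate 2, and Csf1r at 0.04 without HSU replicate 2b and 0.29 without HSU replicate 3b. Endothelial genes had a median of -0.02 (adjusted p = 0.738). Von Willebrand factor (Vwf) was the only endothelial gene to pass adjusted over the list alone (0.41 ± 0.08 higher, adjusted p = 0.0384), and the tight junction gene Cldn5 differed by -0.14. Angiogenic factors had a median of -0.01 (adjusted p = 0.369), with the endothelial proteoglycan Esm1 at -1.23 ± 0.30. Vasoactive genes had a median of -0.02 (adjusted p = 0.294), and Ptgis alone passed adjusted over the list alone (adjusted p = 0.00069). BMP and TGF-beta genes had a median of 0.02 (adjusted p = 0.624), with Tgfb3 at -1.63 ± 0.33 and Tgfb1 at 0.43 ± 0.13. HIF targets had a median of -0.03 (adjusted p = 0.12), with the glycolytic enzyme Eno1 at -0.44.

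Alveolar type I markers had a median of 0.04 (adjusted p = 0.0688), with Gprc5a and the water channel Aqp5 each 0.29 higher and past the threshold adjusted over the list alone (adjusted p = 0.0108). Alveolar type II markers had a median of -0.06 (adjusted p = 0.624) and ciliated cell markers of -0.10 (0.807). Airway secretory markers had a median of -0.22 (adjusted p = 0.263), although their scores separated the groups, and Bpifa1 was at 13.30, 12.22 and 9.61 on the HSU arrays and between 6.00 and 9.78 in HSU_Sor, while the secretoglobin Scgb3a1 differed by -0.99. Immune lists gave medians of -0.02 for T and NK cells (adjusted p = 0.111), 0.00 for B and plasma cells (0.12), -0.01 for neutrophils (0.624) and -0.01 for inflammation genes (0.746). Platelet genes had a median of -0.01 (0.848), immediate early genes of 0.00 (0.624), clock genes of 0.14 (0.104), adipocyte genes of -0.05 (0.0688), mesothelial genes of 0.09 (0.153) and skeletal muscle genes of -0.01 (0.624). Few members were above the filter for B and plasma cells (1 of 8), neutrophils (3 of 8), platelets (1 of 6) and skeletal muscle (3 of 12). Their medians come mostly from probe sets near the floor. The B and plasma cell gene above the filter, Jchain, was 0.97 higher and did not pass adjusted over the list alone (limma, adjusted p = 0.137). The camera direction was up for endothelial, inflammation and neutrophil genes, whose medians were below 0, and for BMP and TGF-beta genes, whose mean was -0.06. The neutrophil mean was 0.17.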

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

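The counts of splits for changed probe sets and for list shifts, the fit with a cardiac term, the fit without HSU 1b and 2b, the letter in the titles and the MHC haplotype test were chosen after the results were seen. In the 4 HSU_Sor arrays, 89 genes and list scores were searched for an array far from the other 3, and 5 had one. Chance gives about 1 in 20, or 4 of 89. Actg2 was at 11.52 on HSU_Sor 2 and between 12.02 and 12.06 on the others. Ecm2 was at 8.82 on HSU_Sor 3 and between 9.01 and 9.04 on the others. Vwf was at 12 on HSU_Sor 4 and between 12.25 and 12.29 on the others. Aqp5 was at 13.30 on HSU_Sor 2 and between 13.10 and 13.13 on the others. Mb was at 2.64 on HSU_Sor 4 and at 2.63 on the others, at the floor of the measurement. Groups of 3 were not searched.

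For the lower smooth muscle and matrix transcripts, of the 35 splits of the 7 arrays, 1, the real one, shifted the smooth muscle list's mean by as much as 0.51 (the highest other split gave 0.51 when rounded), and 1 shifted the matrix list's by as much as 0.49 (highest other 0.45). Since both lists were picked from 32 for their small p on these same arrays, this count does not exclude chance for them. With the cardiac score of each array as a term in the fit, the smooth muscle median was -0.38 (adjusted p = 5.82e-07) and the matrix median -0.31 (adjusted p = 1.03e-07), against -0.49 and -0.46 without it, with an unadjusted p of 0.0902 and 0.031 at an estimated correlation, and without HSU 1b and 2b, which leaves a lone HSU array, the medians were -0.46 and -0.32 while the cardiac list's was 0.01. The cardiac score includes Ankrd1, which was high on all HSU arrays, so the cardiac term itself holds part of the group difference. Both of these fits rest mainly on HSU 3b, the 1 HSU array with a low cardiac score. With the cardiac term the interferon median, carried by this array, went from -0.51 to -1.34. On HSU 3b, at a cardiac score of -0.57, the smooth muscle score was 0.32 and the matrix score 0.24, each above every HSU_Sor array. As this is 1 array, a source in heart muscle, or in tissue near it without heart muscle, stays open, whole or in part. HSU 1b and 2b also held the MHC signal described below, and HSU 3b is the only HSU array without it. A difference in strain or colony, or an exchanged sample, therefore stays open for these 2 lists as well. Titles of all HSU arrays carry the letter b and those of HSU_Sor do not, 0 groups hold both kinds, and a batch that follows this letter cannot be told apart from sorafenib, whose effect also stays open.

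Chance could not be excluded for the counts of probe sets at 1.4-fold and of gene lists. For the 131 probe sets at 1.4-fold and p below 0.01, 3 of 35 splits gave as many, the highest 247 for HSU 3b, HSU_Sor 1 and HSU_Sor 3 against the rest, the 3 arrays with the highest scores on the first principal component (3.4, 21.8 and 29.5). For the 12 gene lists called, 4 of 35 splits called as many, the highest other 14. For the 0 probe sets past the adjusted threshold with limma (931 at an unadjusted p below 0.05 and 42 with SAM, neither counted over the splits), the highest other split gave 1, and as each of the 35 splits has at least 0 the count of splits decides nothing.

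The second pattern is an MHC signal on HSU 1b and 2b. A probe set of the class II gene RT1-Bb was at 12.57 on both and between 3.55 and 3.72 on the other 5 arrays, while another probe set of RT1-Bb was between 13.08 and 14.06 on all 7, and a class I probe set of RT1-CE5 was at 11.05 and 11.45 against 2.71 to 2.82. Higher MHC gene activity through interferon or antigen presentation signals would raise genes such as B2m, Cd74 and Tap1 on this pair. The median gap of 10 such genes was -0.70 and the highest -0.15, so none was higher on both arrays than on all the other 5. The gap was taken from the lower of the pair to the highest of the other 5 arrays. It is below 0 unless both arrays of the pair lie above all 5. HSU 3b, with an interferon score of 1.36, was among those 5 and widened the gap, as for Tap1 at 10.16 there. The size of the gap therefore does not measure the pair alone, and by itself it does not decide on this explanation. Against the HSU_Sor arrays alone the genes went both ways. Psmb9 was lower on the pair (11.12 and 11.22 against 11.41 to 11.93) and Ciita higher (6.97 and 6.56 against 6.11 to 6.47). Over all probe sets, 4 separated the pair from the rest by at least 4 on the log2 scale, against 1 at most for any of the other 20 pairs, and 3 of the 3 with a single gene symbol were RT1 genes. A candidate explanation is a different MHC haplotype in the 2 animals, through strain, colony or an exchanged sample, none of which was tested, and every sample kept its label.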

How the results depend on the processing

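Alternatives that leave out pairs of arrays and the 4 lists written after the values were seen were chosen after seeing the data. The count of changed probe sets, 0 in the fit reported, was 6 with probe sets above the 75th percentile alone, 42 with SAM and 10 without the HSU arrays 1b and 2b, where the lone HSU array is assumed to vary like the HSU_Sor arrays. Leaving out each array in turn gave 0 to 6, the 6 without HSU replicate 3b (MHC genes among them), and the lowest adjusted p over the limma alternatives ranged from 1.13e-06 to 0.616. The 131 probe sets at 1.4-fold became 87 above the 75th percentile, 262 without HSU 1b and 2b, 215 without HSU_Sor 3 and 4, and 105 to 143 without each array. The 12 gene lists became 0 with an estimated correlation, 7 without HSU 1b and 2b and 7 to 15 without each array (7 without HSU_Sor replicate 2), and 3 of the 4 later lists were called (0 of 4 with an estimated correlation). Smooth muscle and matrix lists kept their direction in every alternative run on lists (medians -0.57 to -0.35 and -0.55 to -0.32) and their call in all but the estimated correlation. Acta2, at -0.04, turned to 0.03 with quantile normalization, to 0.22 without HSU 1b and 2b and ranged from -0.17 to 0.04 without each array. Without HSU 1b and 2b, Csf1r was at -0.06, Kdr at -0.02, Mb at 0.06 and the cardiac list at 0.01, and without HSU_Sor 3 and 4 Hbb was at 0.10. The interferon list ranged from -0.75 to -0.01 without each array. No named gene passed in the fit reported. Over all alternatives, 973 of their values kept direction without passing, 4 passed and 10 reversed. Of the lists' values, 404 stayed on their side of the threshold, 21 passed, 51 lost the call and 2 reversed. Direction was not compared where a list was called in neither fit. Beyond fewer arrays, the cause was not tested. HSU and HSU_Sor share no replicate label once the letter b is kept. As nothing in the labels pairs the animals, the fit had no block. Ignoring the letter, deviations of same-numbered arrays correlated at -0.06, 0.18 and 0.14, and those of differently numbered arrays at -0.17 to 0.24. A replicate block gave 0, 147 and 13 for the 3 counts. Probe sets near the floor carry little signal over background, which limits what can be said of dim genes.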

Other observations

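Sterol synthesis genes, pericyte markers and LXR targets were written as lists, and tested, after the values were seen. Of 20 sterol synthesis genes, 18 were lower in HSU_Sor (median -0.23, limma camera adjusted p = 1.57e-07, adjusted p = 0.149 with an estimated correlation). The isomerase Idi1 was at 11.19 ± 0.35 in HSU and 10.14 ± 0.20 in HSU_Sor and passed adjusted over the list alone (adjusted p = 0.0276). The demethylase Cyp51 differed by -0.81 ± 0.21 (SE) and did not pass (adjusted p = 0.0619). LXR targets rose as a list of 9 (median 0.30, adjusted p = 7.56e-05, adjusted p = 0.0947 with an estimated correlation), with Abca1 past its threshold adjusted over the list alone (adjusted p = 0.00796) and Apoe at 0.77 ± 0.25. Pericyte markers fell as a list of 12 (median -0.61, adjusted p = 0.000184, adjusted p = 0.0947 with an estimated correlation), and 5 passed adjusted over the list alone, among them Gjc1 (adjusted p = 0.00214) and Higd1b (adjusted p = 0.0224). Liver genes had a median of -0.01 over 20 genes, with a mean of 0.25 and the camera direction up (adjusted p = 0.326). A lower sterol synthesis programme with sorafenib is a hypothesis from these values that they do not test. The list's mean fell by 0.36, the highest other of the 35 splits giving 0.34, and 1 split, the real one, gave as much, but the list was written from the values of these arrays.

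Single arrays stood apart in other genes. Albumin (Alb) was at 12.38 on HSU_Sor 1 and between 6.76 and 8.14 on the other 6 arrays, and Rup2 was at 8.47 there and between 2.70 and 2.82 on the others, while the liver transcripts Apoa1 and Fgb stayed at 2.21 and 2.78 on HSU_Sor 1. Apoc3 was at 3.56 on HSU_Sor 1 and between 2.79 and 2.82 on the others, and Ttr was at 3.22 against 2.71 to 2.79. The red cell enzyme Alas2 was at 2.76 and 2.79 on HSU_Sor 3 and 4 and between 8.41 and 11.45 on the other 5, and the platelet factor Pf4 was at 8.74 and 8.10 on those arrays against 9.43 to 11.07. Egr1 was at 13.00 on HSU_Sor 2 and between 9.22 and 11.44 on the others. The neurotrophin receptor Ntrk2 was at 8.76 and 8.40 on HSU_Sor 1 and 2 and between 11.74 and 12.82 on the others. Xist lay between 2.64 and 2.69 and the Y-linked Uty between 10.73 and 11.10 on all 7 arrays. The first principal component held 27.4% of the variance and did not separate the groups (two-sided exact permutation p = 0.229). The second held 22.5% and separated them, with an exact p of 0.0571, the smallest that 3 against 4 arrays can give. It had the lowest p of the 6 components tested, and HSU 1b at 7.4 lay near HSU_Sor 1 at 3.5.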
